A study of Rattus norvegicus with 20 samples.

How the data were processed

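MicroRNA levels were measured on 20 single-colour (Cy3) Agilent arrays of female rat temporomandibular joint tissue, 4 per group, from RNA extracted with a mirVana kit per the labels' protocols. Groups were taken from the sample titles: left side at 0, 4 and 8 weeks and right side at 4 and 8 weeks. The scanner files were deposited as spot intensity values that the authors made with Agilent Feature Extraction (named in the submitters' processing notes), version 10.7.1.1 per the file headers. The local background was not subtracted spot by spot, and a fitted background surface and spatial trend were removed within each array, per the file headers. No normalization between arrays is recorded for them. The authors also deposited a single value per miRNA and array, on what appears to be a log2 scale, in a separate value table. Each of its 20 columns correlated best with its own array (Spearman 0.704 to 0.91 over miRNAs), which settles columns and direction. Over detected miRNAs its values rose by 0.928 to 1.39 per log2 unit of the array's probe total, against 0.693 for a natural and 0.301 for a base 10 logarithm, so they were read as log2, while its centring, and how values were normalized between arrays, stay unknown and are not given in the sources used here. The deposited columns had medians of -2.96, -3.26, -3.31 and -2.88 on the log2 scale in replicates 1 to 4 of left 0 weeks, -3.12, -3.12, -3.10 and -2.92 in left 4 weeks, -3.22, -3.01, -3.20 and -3.00 in right 4 weeks, -3.29, -3.12, -2.26 and -3.21 in left 8 weeks, and -3.32, -3.26, -3.22 and -3.24 in right 8 weeks.

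Each array held 12843 features, of which 12128 were not controls, and these carried 1806 probes for 758 miRNAs, with 4 to 16 spots per probe. Control spots and spots with outlier flags (8.15 to 9.65% per array) were left out, and 0 spots were saturated. Spots of a probe were averaged. Because most probes were not well above background, each array's processed signal was divided by its 75th percentile over the 168 probes well above background on all 20 arrays. A floor of 0.0142, or -6.14 on the log2 scale, was then set on the scaled signal: the median over the arrays of each array's 1st percentile among its probes well above background. A probe counted as well above background where at least 0.5 of its spots were marked so, and probes so marked on at least 4 of 20 arrays were kept, 496 in all. A miRNA's level was the mean log2 value of its kept probes, over 267 miRNAs, of which 57 had 1 kept probe and 210 had several. In the 8 pairwise comparisons 11 to 30 of these 210 had probes that disagreed in sign, and 0 of those called did. miRNA names are those of the array design without the species prefix. Probe sites are given in the rn4 build that the files name, where 179 of the 267 miRNAs have a site and 18 have several. Gene neighbours came from an annotation table of the GRCr8 assembly, by name only, in which 17 of 19 miRNA genes looked up were found; whether a miRNA lies in an exon or an intron was not analysed here.

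Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), in a fit of the 5 group means over all 20 arrays, and adjusted by Benjamini-Hochberg over the 267 miRNAs at a threshold of 0.05. There were 8 pairwise comparisons and 1 interaction of side and time. Files were read with data.table (version 1.17.8), and statmod 1.5.0 was loaded beside limma. Slide and replicate number, where used as blocks, entered as fixed factors. Of 16 miRNA lists fixed before the data were examined, 12 had at least 3 measured members and were tested with camera at its preset correlation of 0.01: skeletal and cardiac muscle, cartilage, erythroid, leukocyte, vascular, fibroblast and matrix, neuronal, the miR-17-92 and paralogous clusters, the let-7 family, the Dlk1-Dio3 cluster, and literature lists of arthritis and of mechanical loading. The epithelial, gland, HOX cluster and miR-34 lists were too small. A miRNA not well above background on any array of a group has only a bound there. Counts of detected miRNAs were compared by exact two-sided permutation tests. The number of arrays, 4 per group, limits the precision: the median 95% confidence interval of a fold change reached 0.73 to either side on the log2 scale, and 1.03 for the interaction.

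The miRNAs named were chosen by a rule written before the data were examined. For each pairwise comparison these were up to 10 higher and 10 lower with the largest fold change among those past the threshold whose groups did not overlap. Where fewer than 3 passed, the 3 with the smallest p in each direction were added, and for the interaction up to 5 in each direction. Members of a list that passed were added, as were 20 miRNAs fixed by name, of which 19 were kept and miR-200c-3p was not.

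The steps were tested on simulated data built from the 267 miRNAs of these arrays, with 20 simulations per comparison and 25 miRNAs changed at each size. Changes of 2-fold were recovered in 43.2% (left 4 against 0 weeks), 42.6% (left 8 against 0), 44.4% (right 4 against 0), 38.4% (right 8 against 0), 39.8% (right against left at 4), 45.0% (at 8), 42.6% (left 8 against 4), 42.6% (right 8 against 4) and 20.0% (interaction) of cases. For 4-fold changes the shares were 71.2, 67.4, 73.2, 70.8, 71.8, 76.4, 69.0, 71.4 and 53.6% in the same order, and for 8-fold changes 78.6, 78.0, 75.4, 77.4, 78.6, 78.0, 76.2, 76.4 and 66.2%. These shares include falls cut short by the floor. Among rises, and falls that stayed above the floor, 8-fold changes were recovered in 94.3 to 97.3% (pairwise) and 85.8% (interaction) of cases. False discoveries made up 3.35 to 5.47% of calls, and with no change at most 0.15 miRNAs were called on average. A 21-member list shifted by 1 on the log2 scale was found in 20 of 20 simulations in each comparison. With no change, the lists called over 20 simulations numbered 4 for left 4 against 0, 3 for right 8 against left 0, 3 for left 8 against left 4 and 5 for right 8 against right 4 weeks. They numbered 0 in the other comparisons. The simulated miRNAs varied independently of each other, unlike real ones.

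The slide of each array was read from the file headers: slide 1 held 1 left 0-week and 1 right 8-week array, slide 2 held 3 left 0-week, 2 left 8-week and 3 right 8-week arrays, slide 3 held 2 left 4-week, 4 right 4-week and 2 left 8-week arrays, and slide 4 held 2 left 4-week arrays. The arrays of 0 and 4 weeks shared no slide and were linked through left 8 weeks. Replicate numbers recur across groups, and arrays with the same number did not all deviate together, so the numbers were not taken as pairs. The 30 pairs of replicates within groups correlated at 0.74 to 0.994 and shared 0 identical probe values.

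Alternatives fixed before the data were examined covered the scaling percentile, quantile normalization, the normexp background with an offset of 50, the brightest probe per miRNA, the software's gene total, the authors' value table, no filter and a stricter filter on dim probes (10 of 20 arrays), only the arrays compared, no intensity trend, array weights, slide and replicate number as blocks, each array left out in turn, fry and an estimated correlation for lists, and split 0-week arrays. Alternatives added after seeing the data were the software's probe total, only miRNAs well above background on all 20 arrays, centring on the median miRNA, the dimmest and brightest array left out together, array brightness as a covariate, and single slides. The software's gene total was at fault: 1223 of 5115 detected totals (23.9%) exceeded 1.2 times the sum of their own probes, and 1077 of these equalled the preceding detected miRNA's total plus their own within 10%. No column of per-sample values was left unused.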

Results

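Mature microRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured on 20 single-colour arrays of rat temporomandibular joint tissue, the jaw joint in front of the ear. The titles give 5 groups of 4 arrays: the left side, titled as chewing inability, at 0, 4 and 8 weeks, and the right side, titled as excessive mastication, at 4 and 8 weeks. The design text mentions sham-operated controls, but no label marks an array as one, so the left 0-week group served as the reference for every group. Its deposited files carry letters in their names unlike those of the other left groups, which no label explains, so the side of this group rests on its titles. No untreated arrays of 4 or 8 weeks were analysed here, so time and treatment could not be separated in these comparisons. No right 0-week array was among the 20 either, so the right groups against left 0 weeks also differ in side. Between the sides at 4 or 8 weeks, treatment and side could not be separated. The labels do not say that replicates are separate animals or that a left and a right array came from the same animal. The p-values therefore measure only the spread between these samples, which may be technical.

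Of 758 miRNAs on the array, 267 were kept, and levels are log2 values relative to each array's own 75th percentile of well-detected probes. The number of miRNAs well above background was 219 ± 44.2 (SD, n = 4) at left 0 weeks, 204 ± 14.9 at left 4 weeks, 215 ± 16.4 at right 4 weeks, 200 ± 58.2 at left 8 weeks and 258 ± 37.0 at right 8 weeks. It ranged from 118 in left 8 weeks replicate 3, whose scaling signal was 134.9, to 313 in right 8 weeks replicate 1, whose scaling signal was 9159. Across 8 pairwise comparisons, the smallest exact two-sided permutation p for this number was 0.0286, for right 8 against right 4 weeks (a difference of 43), which is the smallest 4 against 4 arrays can give, and its Benjamini-Hochberg value was 0.229. The share of miRNAs at the floor was 27.7, 4.5, 6 and 8.2% in the 4 left 0-week arrays and 21.7 to 28.8% in the 8 arrays of 4 weeks. The median log2 fold change of all 267 miRNAs against 0 weeks was -0.38 at left 4, -0.22 at left 8, -0.29 at right 4 and -0.30 at right 8 weeks. Scaling on all probes put these medians at 0.31, 0.02, 0.41 and 0.11, so list values are given relative to the other miRNAs.

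**Figure D1:**
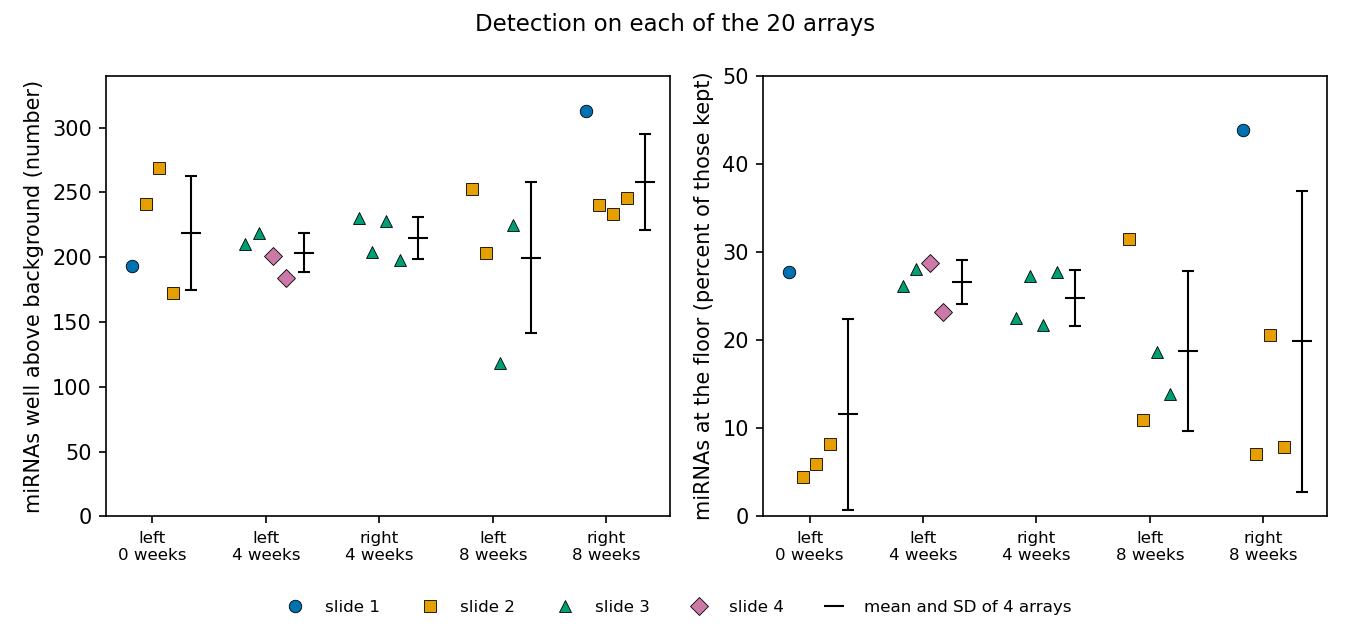
Number of miRNAs well above background (left panel) and percentage of the 267 kept miRNAs at the floor (right panel) in each of 20 arrays, by group and coloured by slide, with the mean and SD of 4 arrays per group. Detected miRNAs ran from 118 to 313, and replicates 2, 3 and 4 of left 0 weeks held 4.5 to 8.2% of miRNAs at the floor.

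The first comparison asked how the left joint at 4 weeks differed from the left joint at 0 weeks. Of the called miRNAs, 3 of 4 in the muscle list and 3 of 3 in the cartilage list rose, and 12 of 12 in the Dlk1-Dio3 list fell. miR-1-3p, characteristic of skeletal and cardiac muscle, rose from -3.21 ± 1.04 to 0.29 ± 1.34 (SD, n = 4 each), a log2 fold change of 3.50 ± 1.07 (SE, limma adjusted p = 0.0367) or 11.3-fold. miR-140-3p, an abundant cartilage miRNA encoded within Wwp2, rose from -1.96 ± 0.51 to 0.03 ± 0.46, or 3.96-fold (adjusted p = 0.0271). miR-770-3p, encoded within Meg3 in the imprinted Dlk1-Dio3 region, fell from -3.92 ± 0.29 to -6.14 ± 0.00 (adjusted p = 0.0011). Only 1 of the 4 arrays of 4 weeks measured miR-770-3p above background, and its level lay at the floor on all 4, which sets the size of the fall.

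At this comparison 58 of 267 miRNAs passed an adjusted p of 0.05, 10 higher and 48 lower, and 31 of them did not overlap between the groups. Over all miRNAs 52 (19.5%) did not overlap, where chance gives 2.86%. Among those higher, miR-1b (3.08 ± 1.08), miR-140-5p (1.56 ± 0.45), miR-503-5p (0.86 ± 0.25), miR-450a-5p (0.76 ± 0.23) and miR-27b-3p (0.76 ± 0.26) rose with every 4-week array above every 0-week array. Of 26 alternatives 21 lost the miR-27b-3p call, 20 the miR-1b call and 11 the miR-140-5p call. miR-503-5p was measured on 3 and miR-450a-5p on 1 of the 0-week arrays. miR-455-5p, a cartilage miRNA encoded within the collagen gene Col27a1, was not well above background on any 0-week array and was at least 1.66-fold higher at 4 weeks (adjusted p = 0.00634). The direction turned for miR-455-5p (-0.15) and miR-450a-5p (-0.21) with the normexp background, and for miR-450a-5p (-0.33) with the software's gene total. Such bounds set the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own. Among those lower, miR-211-3p fell by 3.24 ± 0.99, miR-1224 by 2.67 ± 0.73, miR-134-5p by 2.50 ± 0.72, miR-3593-3p by 2.50 ± 0.76, miR-762 by 2.47 ± 0.80, miR-3564 by 1.70 ± 0.40, miR-434-3p by 1.69 ± 0.38 and miR-347 by 1.68 ± 0.50 on the log2 scale. Of 26 alternatives 18 lost the miR-347 call, and of 25 alternatives 4 lost the miR-3564 call. In the leukocyte list miR-150-3p, from a lymphocyte miRNA gene, fell by 2.54 ± 0.56 (adjusted p = 0.00985), and miR-155-5p, induced in activated immune cells, fell by 1.30 ± 0.43 (adjusted p = 0.0393). The other arm, miR-150-5p, was measured but not called. At 4 weeks miR-155-5p lay at the floor on all arrays but replicate 4 (-6.06), so the floor sets the size of its fall. Of 25 alternatives 15 lost its call.

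Each list fixed in advance was tested with camera against the other miRNAs. The 7 muscle miRNAs lay 1.95 higher (adjusted p = 0.00194), and adjusted p = 0.312 with an estimated correlation. Over all miRNAs 3 members (miR-1-3p, miR-133b-3p and miR-206-3p) were higher and 1 (miR-133c) lower, and adjusted over the list alone 4 were higher and 1 lower. Their shift was 2.85 (adjusted p = 0.0395) with slide as a block, and the call ended with all-probe scaling (adjusted p = 0.271). The 5 cartilage miRNAs lay 1.42 higher (adjusted p = 0.000179), and adjusted p = 0.134 with an estimated correlation. Over all miRNAs, and adjusted over the list alone, 3 cartilage members were higher and 0 lower, and the shift with the slide block was 2.0 (adjusted p = 0.00897). Of the 21 measured miRNAs of the Dlk1-Dio3 region, 12 were lower and 0 higher over all miRNAs (13 and 0 adjusted over the list alone), but with all-probe scaling 2 were lower and 2 higher. The cluster lay -0.56 from the other miRNAs (adjusted p = 0.000289), and adjusted p = 0.436 with an estimated correlation; with the slide block it lay at -0.58 (adjusted p = 0.0395). The 8 fibroblast and matrix miRNAs lay 0.64 higher (adjusted p = 0.0186), and adjusted p = 0.436 with an estimated correlation, with 0 members called over all miRNAs or adjusted over the list alone. The 10 miRNAs of the miR-17-92 and paralogous clusters, linked to cell proliferation, lay 0.69 higher (adjusted p = 0.00643), and adjusted p = 0.548 with an estimated correlation, again with 0 members called either way. With the slide block the fibroblast and miR-17-92 shifts were 1.31 (adjusted p = 0.0177) and 1.79 (adjusted p = 0.000112), and without left 0 weeks replicate 4 the fibroblast call ended (adjusted p = 0.179). The erythroid, leukocyte, vascular, neuronal, let-7, arthritis and mechanical loading lists missed the threshold, with adjusted p from 0.188 to 0.951, though with the slide block the erythroid list lay 3.19 higher (adjusted p = 0.00189; 0.77 without it) and the arthritis list 0.86 higher (adjusted p = 0.048). The slide-block values depend on left 8 weeks, the only group on both slides 2 and 3. Its replicate 2 lay highest for the miR-17-92 list and for the erythroid list (-1.51, against -3.63 to -4.84 in its other arrays). Of leukocyte members 2 were lower over all miRNAs and 2 adjusted over the list alone. The arthritis list held 3 higher and 1 lower member by both adjustments. Of neuronal members 1 was lower over all miRNAs, against 1 higher and 3 lower adjusted over the list alone, and 1 mechanical loading member was lower over all miRNAs and 0 adjusted over the list alone.

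The remaining miRNAs fixed by name missed the threshold, among them miR-133a-3p (1.89 ± 0.81, adjusted p = 0.0963), miR-21-5p (0.52 ± 0.41), miR-146a-5p (-0.72 ± 0.46), miR-223-3p (-0.64 ± 0.32), miR-451-5p (0.71 ± 0.82), miR-210-3p (0.72 ± 0.63), miR-142-3p (0.28 ± 0.50) and miR-34a-5p (-0.31 ± 0.34). miR-124-3p, well above background on 2 arrays of 0 weeks and 0 of 4 weeks, was at least 1.44-fold lower and missed it too (adjusted p = 0.0653). miR-455-3p (0.14 ± 0.35), miR-126a-3p (0.07 ± 0.57), miR-145-5p (0.09 ± 0.61) and miR-29b-3p (0.04 ± 0.48) lay closer to 0. No slide held arrays of both groups, and with slide as a block 91 miRNAs passed (6 higher, 85 lower). The split of calls was 20 higher and 13 lower with all-probe scaling, 8 and 7 with quantile normalization, 22 and 13 with arrays centred on the median miRNA and 0 and 0 with the normexp background. Leaving out replicates 1, 2, 3 or 4 of left 0 weeks gave 95, 13, 9 and 21 calls, and leaving out those of left 4 weeks gave 11, 11, 12 and 14.

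**Figure D2:**
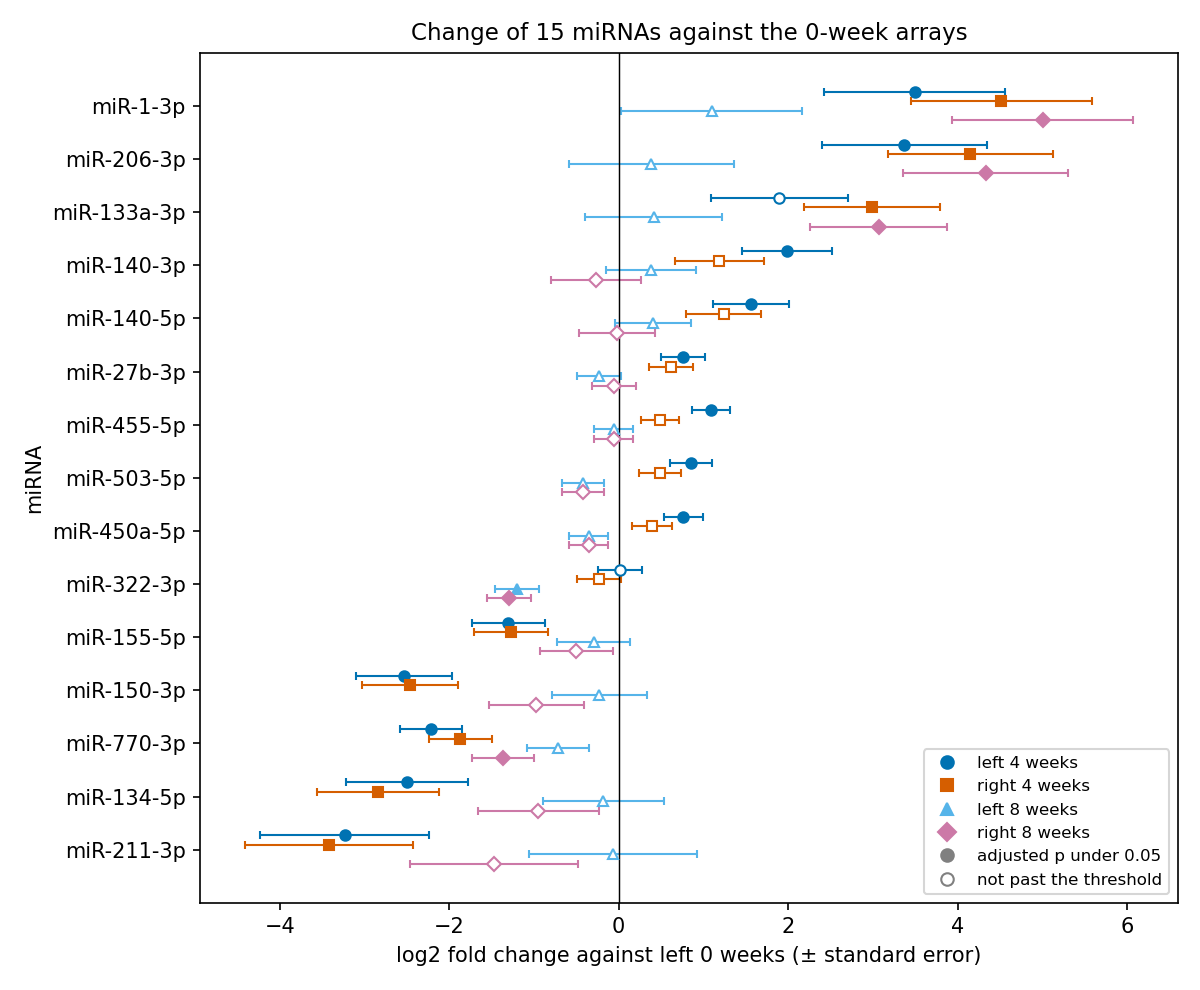
Log2 fold change against left 0 weeks, with its standard error, of 15 miRNAs in the 4 other groups (4 arrays each), filled where the limma adjusted p was under 0.05. miR-1-3p stood at 3.50, 4.52 and 5.0 in left 4, right 4 and right 8 weeks, and miR-770-3p at -2.22, -1.87 and -1.36.

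The second comparison asked whether the left joint at 8 weeks differed from 0 weeks. miR-322-3p, of the X-linked miR-322 and miR-503 cluster, fell from -4.73 ± 0.45 to -5.93 ± 0.23 (SD, n = 4 each), 2.30-fold lower (limma adjusted p = 0.0463), with every 8-week array below every 0-week array. Of 26 alternatives 19 lost its call, and it was well above background on 3 arrays of 0 weeks and 2 of 8 weeks. It was the 1 miRNA of 267 that passed, while 29 had an unadjusted p under 0.05 and 9 (3.37%, chance 2.86%) did not overlap. Next by p were miR-299a-5p (-1.03 ± 0.24, adjusted p = 0.0527) and miR-138-1-3p (-0.44 ± 0.11, adjusted p = 0.0676) on the lower side. On the higher side stood 3 members of the miR-29 family, which targets collagen messenger RNAs: miR-29a-3p (0.63 ± 0.28, adjusted p = 0.411), miR-29c-3p (0.81 ± 0.40) and miR-29c-5p (at least 1.1-fold).

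Among lists, the 21 Dlk1-Dio3 miRNAs lay -0.37 from the other miRNAs (adjusted p = 1.26e-05), and adjusted p = 0.42 with an estimated correlation. Over all miRNAs 0 passed and adjusted over the list alone 7 were lower, and the shift was -0.39 (adjusted p = 0.0022) with the slide block and -0.41 (adjusted p = 0.011) within slide 2. With the normexp background, 15 of the 21 had fold changes above 0. The 7 muscle miRNAs lay 0.57 higher (adjusted p = 0.0168), and adjusted p = 0.42 with an estimated correlation. The 4 erythroid miRNAs, among them the red-cell miRNAs miR-451-5p and miR-144-3p, lay 0.81 higher (adjusted p = 0.0032), and adjusted p = 0.42 with an estimated correlation. The 10 miRNAs of the miR-17-92 and paralogous clusters lay 0.27 higher (adjusted p = 0.0243), and adjusted p = 0.598 with an estimated correlation. In these 3 lists 0 members passed over all miRNAs or adjusted over the list alone. With the slide block their shifts were 1.04 (adjusted p = 0.0236), 2.11 (adjusted p = 6.75e-07) and 0.95 (adjusted p = 6.75e-07), and within slide 2 they were 0.94 (adjusted p = 0.0107), 2.11 (adjusted p = 5.07e-06) and 0.94 (adjusted p = 4.87e-06). The muscle call ended without replicate 2 (shift 0.49, adjusted p = 0.0677) or 3 (0.37, 0.132) of left 0 weeks or replicate 1 (0.28, 0.219) or 3 (0.72, 0.0812) of left 8 weeks. The erythroid call ended without replicate 3 of left 0 weeks (0.52, 0.0829) or replicate 1 (0.66, 0.0868) or 2 (0.14, 0.411) of left 8 weeks. The miR-17-92 call ended without replicate 3 (0.17, 0.161) or 4 (0.19, 0.17) of left 0 weeks or replicate 1 (0.19, 0.219) or 2 (0.0076, 0.935) of left 8 weeks, so left 8 weeks replicate 2 carried most of the erythroid and miR-17-92 shifts. The other 8 lists missed the threshold, with adjusted p from 0.13 to 0.867, though the fibroblast list lay 0.70 higher with the slide block (adjusted p = 0.0022) and 0.72 higher within slide 2 (adjusted p = 0.000433).

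Among miRNAs fixed by name, miR-1-3p stood at 1.1 ± 1.07, miR-206-3p at 0.39 ± 0.97, miR-133a-3p at 0.41 ± 0.81, miR-140-3p at 0.38 ± 0.53, miR-140-5p at 0.40 ± 0.45, miR-451-5p at 0.71 ± 0.82 and miR-34a-5p at -0.77 ± 0.34, none past the threshold. The others lay between -0.85 (miR-126a-3p) and 0.69 (miR-29b-3p). Within slide 2 (2 against 3 arrays) 0 passed, and with the slide block 6 did. Leaving out replicate 1 or 4 of left 0 weeks gave 4 and 7 calls, and leaving out replicate 2 or 3 of left 0 weeks, or replicate 1, 3 or 4 of left 8 weeks, gave 0.

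The third comparison set the right joint at 4 weeks against the left joint at 0 weeks. Muscle miRNAs rose again: miR-1-3p was 22.9-fold higher (4.52 ± 1.07, SE, n = 4 each; limma adjusted p = 0.0171), miR-206-3p 17.8-fold higher (4.15 ± 0.97, adjusted p = 0.0171) and miR-133a-3p 7.94-fold higher (2.99 ± 0.81, adjusted p = 0.028). Their groups overlapped, since right 4 weeks replicate 3 lay at -2.39 for miR-1-3p where the other 3 arrays lay at 2.22 or above. miR-128-3p, abundant in brain and muscle, rose from -5.73 ± 0.10 to -4.19 ± 0.40 (SD; adjusted p = 0.0058) and miR-30a-3p from -5.78 ± 0.15 to -4.12 ± 0.66 (adjusted p = 0.0171). miR-378a-5p, encoded within a regulator of energy metabolism, was not well above background at 0 weeks and was at least 3.03-fold higher (adjusted p = 0.028). miR-331-3p fell from -4.42 ± 0.14 to -5.90 ± 0.21 and miR-770-3p from -3.92 ± 0.29 to -5.79 ± 0.41 (adjusted p = 0.0058 each). With the gene total miR-128-3p (-0.88) and miR-331-3p (0.13) turned.

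In total 44 miRNAs passed, 12 higher and 32 lower, and 18 of them did not overlap; over all miRNAs 38 (14.2%) did not overlap, where chance gives 2.86%. miR-30a-5p (1.18 ± 0.37) and miR-30b-5p (0.88 ± 0.28) also rose. miR-211-3p fell by 3.42 ± 0.99, miR-1224 by 2.91 ± 0.73, miR-134-5p by 2.84 ± 0.72, miR-762 by 2.80 ± 0.80, miR-3593-3p by 2.50 ± 0.76, miR-150-3p by 2.46 ± 0.56 and miR-3564 by 1.64 ± 0.40 on the log2 scale. miR-122-5p, the main liver miRNA, was not well above background on any right 4-week array and was measured 2.82-fold lower (adjusted p = 0.0413). Here the bound equals the measured change, and 12 of 25 alternatives lost the call, with a fold change as small as -0.62 on the log2 scale. miR-155-5p fell by 1.27 ± 0.43 (adjusted p = 0.0498), and 18 of 25 alternatives lost its call. miR-140-3p (1.19 ± 0.53, adjusted p = 0.106), miR-140-5p (1.24 ± 0.45, adjusted p = 0.0575) and miR-27b-3p (0.61 ± 0.26, adjusted p = 0.0932) did not pass, nor did the others fixed by name, which lay between -0.58 (miR-124-3p, at the floor on all right 4-week arrays) and 1.09 (miR-451-5p).

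The 7 muscle miRNAs lay 2.57 above the other miRNAs (adjusted p = 0.00163), and adjusted p = 0.476 with an estimated correlation. Of them 5 were higher and 1 (miR-133c) lower, over all miRNAs and adjusted over the list alone, and with the slide block the shift of 3.45 missed the threshold (adjusted p = 0.0506). The cartilage list lay 0.99 higher (adjusted p = 0.0142), and adjusted p = 0.476 with an estimated correlation, with 0 members called over all miRNAs and 2 higher adjusted over the list alone. Its shift was 1.45 with the slide block (adjusted p = 0.0876), and its call ended without right 4 weeks replicate 4 (adjusted p = 0.0703). The miR-17-92 list lay 0.85 higher (adjusted p = 0.00163), and adjusted p = 0.476 with an estimated correlation, and 2.05 higher with the slide block (adjusted p = 4.69e-05). The erythroid list lay 1.24 higher (adjusted p = 0.0487), and adjusted p = 0.476 with an estimated correlation, and 3.78 with the slide block (adjusted p = 0.00132). The erythroid and miR-17-92 values with the slide block depend on left 8 weeks, where replicate 2 was the highest array for both lists. The fibroblast list lay 0.62 higher (adjusted p = 0.0467), and adjusted p = 0.476 with an estimated correlation, and 1.29 with the slide block (adjusted p = 0.0491). In these last 3 lists 0 members were called over all miRNAs or adjusted over the list alone. The erythroid call ended without left 0 weeks replicate 1 (adjusted p = 0.0982) or 3 (0.116) or right 4 weeks replicate 3 (0.285), and the fibroblast call without left 0 weeks replicate 2 (0.0504) or 4 (0.224) or right 4 weeks replicate 4 (0.0804). Of the Dlk1-Dio3 cluster 3 members were lower over all miRNAs and 12 adjusted over the list alone, while with all-probe scaling 1 was higher and 2 lower. Its shift was -0.53 (adjusted p = 0.00163), and adjusted p = 0.476 with an estimated correlation, or -0.58 with the slide block (adjusted p = 0.0876). The other 6 lists missed the threshold, with adjusted p from 0.135 to 0.918.

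The right 4-week arrays all lay on slide 3, which held no 0-week array, and with slide as a block 105 miRNAs passed (18 higher, 87 lower). The split of calls was 21 higher and 15 lower with all-probe scaling, 11 and 14 with quantile normalization, 28 and 19 with median centring and 4 and 2 with the normexp background. Leaving out replicates 1, 2, 3 or 4 of left 0 weeks gave 102, 12, 3 and 19 calls, and leaving out those of right 4 weeks gave 12, 3, 23 and 3.

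The fourth comparison set the right joint at 8 weeks against the left joint at 0 weeks. Muscle miRNAs again showed the largest rises, with every right 8-week array above every 0-week array: miR-1-3p rose from -3.21 ± 1.04 to 1.79 ± 1.46 (SD, n = 4 each), 32.1-fold (limma adjusted p = 0.0145). miR-1b (4.39 ± 1.08), miR-206-3p (4.33 ± 0.97), miR-133b-3p (4.19 ± 0.96) and miR-133a-3p (3.07 ± 0.81) rose likewise. The remaining rises were those of miR-30a-3p (1.56 ± 0.40), miR-128-3p (1.17 ± 0.29) and miR-29c-5p, which was not well above background at 0 weeks and at least 1.70-fold higher (adjusted p = 0.0145). The direction of miR-128-3p turned with the normexp background (-0.048) and the gene total (-1.29), and that of miR-29c-5p with the normexp background (-0.15). On the lower side, miR-322-3p fell by 1.29 ± 0.26 and the Dlk1-Dio3 miRNA miR-329-3p by 1.09 ± 0.24 (adjusted p = 0.0145 each). miR-770-3p fell by 1.36 ± 0.37, miR-214-3p, from a mesenchymal miRNA gene within Dnm3, by 1.1 ± 0.31 and miR-299a-5p by 0.92 ± 0.24, and miR-329-3p turned with the gene total (1.17). The call was lost in 19 of 27 alternatives for miR-214-3p, 18 of 26 for miR-770-3p and 16 of 26 for miR-299a-5p.

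Of 15 miRNAs past the threshold 8 were higher and 7 lower, and 13 did not overlap; over all miRNAs 29 (10.9%) did not overlap against a chance share of 2.86%. The muscle list lay 2.78 above the other miRNAs (adjusted p = 7.32e-07), and adjusted p = 0.0548 with an estimated correlation. In it 4 members were higher over all miRNAs and 5 adjusted over the list alone. The muscle shift was 2.78 with the slide block (adjusted p = 4.39e-06), 3.38 on slide 1, where 1 array stood against 1, and 2.58 within slide 2 (adjusted p = 0.000534). The Dlk1-Dio3 list lay at -0.42 (adjusted p = 0.00145), and adjusted p = 0.848 with an estimated correlation, with 4 members lower over all miRNAs and 8 adjusted over the list alone. With all-probe scaling 0 Dlk1-Dio3 members passed and the call ended (adjusted p = 0.296). Its shift was -0.42 with the slide block (adjusted p = 0.00751), -0.30 on slide 1 and -0.46 within slide 2 (adjusted p = 0.0248). The other 10 lists missed the threshold, with adjusted p from 0.236 to 0.923, and the fibroblast list held 1 higher (miR-29c-5p) and 1 lower member (miR-214-3p) over all miRNAs and 3 higher and 2 lower adjusted over the list alone. Other miRNAs fixed by name lay between -0.97 (miR-455-3p, adjusted p = 0.121) and 0.63 (miR-451-5p), and miR-140-3p stood at -0.27 ± 0.53.

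Within slide 2 (3 against 3 arrays) 0 miRNAs passed, and with the slide block 12 did. The split of calls was 3 higher and 0 lower with all-probe scaling, 5 and 1 with quantile normalization, 4 and 0 with the normexp background and 9 and 0 with median centring. Leaving out replicates 1, 2 or 3 of left 0 weeks gave 28, 7 and 1 calls, and leaving out replicates 1, 3 or 4 of right 8 weeks gave 5, 0 and 6. Right 8 weeks replicate 1 carried the highest share of miRNAs at the floor, 43.8%.

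**Figure D3:**
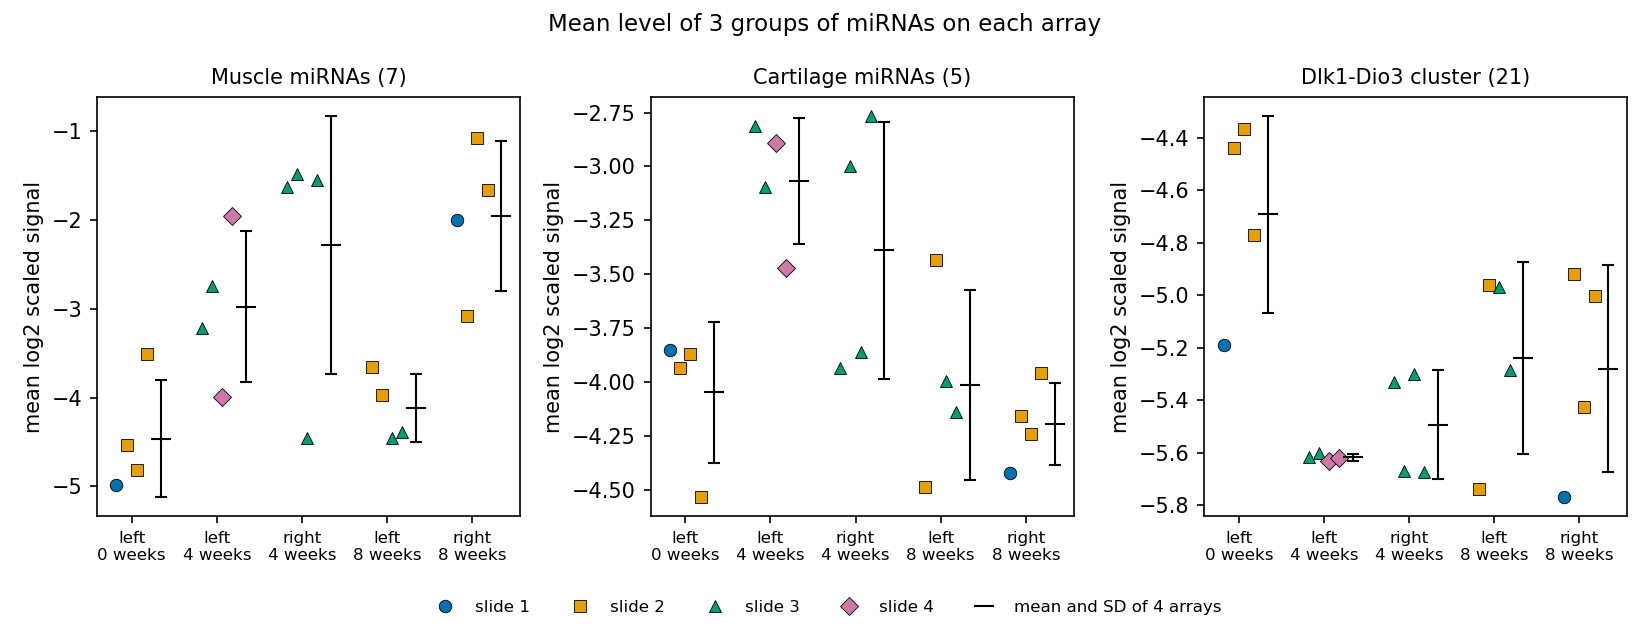
Mean log2 level of the 7 muscle, 5 cartilage and 21 Dlk1-Dio3 miRNAs in each of 20 arrays, by group, with the mean and SD of 4 arrays. The muscle mean ran from -4.46 at left 0 weeks to -1.96 at right 8 weeks, and right 4 weeks replicate 3 lay at -4.46 while its other 3 arrays lay at -1.62 or above.

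The comparison of sides at 4 weeks asked how the right, overused joint differed from the left. No difference passed in limma (0 of 267, smallest adjusted p = 1), while 10 miRNAs had an unadjusted p under 0.05. The lowest p belonged to miR-128-3p (-4.19 ± 0.40 right, -5.04 ± 0.36 left, SD, n = 4 each; 0.84 ± 0.29), miR-675-3p (0.79 ± 0.32) and miR-30a-3p (0.96 ± 0.40) on the higher side, and miR-455-5p (-0.61 ± 0.23), miR-455-3p (-0.67 ± 0.35) and miR-181a-5p (-0.80 ± 0.46) on the lower. The median 95% confidence interval of a fold change reached 0.73 to either side on the log2 scale. On the right the 5 cartilage miRNAs lay at -0.43 relative to the other miRNAs (adjusted p = 0.0221), and adjusted p = 0.684 with an estimated correlation. None of the 5 passed over all miRNAs or adjusted over the list alone (0 each). Their shift was -0.56 with the slide block (adjusted p = 0.0252) and -0.56 within slide 3 (adjusted p = 0.131). That call ended without left 4 weeks replicate 1 (adjusted p = 0.0962) or right 4 weeks replicate 1 (0.121) or 3 (0.769). The other 11 lists missed the threshold, with adjusted p from 0.246 to 0.934, and miR-1-3p stood at 1.02 ± 1.07, miR-133a-3p at 1.09 ± 0.81 and miR-206-3p at 0.78 ± 0.97. Other miRNAs fixed by name lay between -0.80 (miR-140-3p) and 0.46 (miR-223-3p and miR-145-5p). Within slide 3 (4 against 2 arrays), and in every run leaving out 1 array, 0 passed, while array weights gave 29 (22 higher, 7 lower) and the gene total 1.

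At 8 weeks the right joint carried more of the muscle miRNAs than the left as a group. The 7-member list lay 2.21 higher (adjusted p = 0.000179), and adjusted p = 0.225 with an estimated correlation; 0 members passed over all miRNAs and 5 adjusted over the list alone. miR-206-3p stood at 0.52 ± 1.5 on the right and -3.42 ± 1.22 on the left (SD, n = 4 each; 3.94 ± 0.97, limma adjusted p = 0.0751), miR-1-3p at 1.79 ± 1.46 and -2.11 ± 1.75 (adjusted p = 0.0751) and miR-133a-3p at -2.72 ± 1.43 and -5.37 ± 0.22 (adjusted p = 0.103). The list's shift was 1.74 with the slide block (adjusted p = 0.0383) and 1.64 within slide 2 (adjusted p = 0.0406). The lowest p also belonged to miR-378b (2.22 ± 0.57) and miR-128-3p (1.13 ± 0.29) on the higher side and to let-7d-3p (-0.64 ± 0.35), miR-770-3p (-0.64 ± 0.37) and miR-652-5p (-1.22 ± 0.70) on the lower. In limma 0 of 267 miRNAs passed and 16 had an unadjusted p under 0.05. With the slide block 5 passed, within slide 2 (3 against 2 arrays) 0 did, and without right 8 weeks replicate 2, 12 did. The other 11 lists had an adjusted p of 0.966, but the erythroid list lay at -1.58 with the slide block (adjusted p = 0.000159) and within slide 2 (0.000686), and the miR-17-92 list -0.69 (0.000334) and -0.70 (0.000445), against -0.28 and -0.01 without. The erythroid mean on slide 2 was -1.51 in left 8 weeks replicate 2 and -3.63 in replicate 1, against -3.75, -3.54 and -4.25 on the right, so replicate 2 made most of that shift. Other miRNAs fixed by name lay between -0.82 (miR-210-3p) and 1.14 (miR-126a-3p).

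Between 4 and 8 weeks on the left side, miR-503-5p, miR-322-3p, miR-450a-5p and the cartilage miRNA miR-455-5p fell, and miR-150-3p and miR-770-3p rose. miR-503-5p fell from -4.86 ± 0.39 to -6.13 ± 0.01 (SD, n = 4 each; limma adjusted p = 0.00861), miR-322-3p by 1.21 ± 0.26 (SE, adjusted p = 0.0106) and miR-450a-5p by 1.12 ± 0.23 (adjusted p = 0.0106). miR-450a-5p lay at the floor on all 4 arrays of 8 weeks and miR-503-5p on all but replicate 4, so the floor sets the size of their falls. The probe sites of these 3 lay near each other on the X chromosome in the rn4 build that the files name, at 139999883 to 139999897, 140000228 to 140000240 and 139994969 to 139994985. miR-455-5p, whose site lies on chromosome 5 at 80239862 to 80239878, was not well above background on any 8-week array and was at least 1.32-fold lower (adjusted p = 0.00861). miR-150-3p rose from -5.84 ± 0.07 to -3.53 ± 0.79 (adjusted p = 0.0221) and miR-770-3p, from the floor, by 1.5 ± 0.37 (adjusted p = 0.0221).

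In all 11 miRNAs passed, 4 higher and 7 lower, and all 11 did not overlap; over all miRNAs 34 (12.7%) did not overlap against a chance share of 2.86%. miR-3564 (1.60 ± 0.40) and miR-331-3p (1.17 ± 0.29) rose, and miR-335 fell by 1.14 ± 0.28, miR-1949 by 1.0 ± 0.26 and miR-27b-3p by 0.98 ± 0.26. At 8 weeks miR-335 lay at the floor on all arrays but replicate 4 (-6.02), so the floor sets the size of its fall. With the normexp background the fold changes of miR-503-5p, miR-322-3p, miR-450a-5p, miR-455-5p, miR-335 and miR-1949 had the opposite sign, as had miR-770-3p (-0.12) and miR-331-3p (-1.59) with the gene total and miR-331-3p (-0.50) with the authors' value table. The cartilage list lay -1.17 from the other miRNAs (adjusted p = 0.00275), and adjusted p = 0.326 with an estimated correlation. In it 1 member was lower over all miRNAs and 3 adjusted over the list alone, and its shift was -1.45 with the slide block (adjusted p = 0.0221) and -1.45 within slide 3 (adjusted p = 0.000762). The other 11 lists missed the threshold, with adjusted p from 0.243 to 0.816. The miR-17-92 list lay at -0.84 with the slide block (adjusted p = 0.0258) and within slide 3 (0.0163), and the muscle list at -1.80 within slide 3 (0.0261 from the arrays compared alone, missing the threshold with all arrays of that slide). miR-140-3p (-1.61 ± 0.53, adjusted p = 0.0854), miR-206-3p (-2.99 ± 0.97, adjusted p = 0.0854), miR-1-3p (-2.40 ± 1.07), miR-133a-3p (-1.48 ± 0.81), miR-140-5p (-1.16 ± 0.45) and miR-21-5p (-1.08 ± 0.41) did not pass, and other miRNAs fixed by name lay between -0.92 (miR-126a-3p) and 1.01 (miR-155-5p). With the slide block 54 miRNAs passed (48 higher, 6 lower) and within slide 3 (2 against 2 arrays) 44 did (43 higher, 1 lower), a balance opposite to that of the 11. Leaving out replicates 1, 2, 3 or 4 of left 4 weeks gave 4, 4, 2 and 4 calls, and leaving out replicate 1 or 3 of left 8 weeks gave 59 (48 higher, 11 lower) and 4.

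Between 4 and 8 weeks on the right side no single miRNA passed in limma (0 of 267, smallest adjusted p = 0.162), while 24 had an unadjusted p under 0.05. The lowest belonged to miR-322-3p (-4.96 ± 0.41 at 4 and -6.02 ± 0.16 at 8 weeks, SD, n = 4 each; -1.06 ± 0.26), miR-503-5p (-0.91 ± 0.25, adjusted p = 0.222) and miR-450a-5p (-0.75 ± 0.23), the last 2 at the floor on all arrays of 8 weeks, which sets the size of their fall, and on the higher side to miR-23a-5p (0.86 ± 0.27), miR-465-5p (1.66 ± 0.59) and miR-3564 (1.1 ± 0.40). The cartilage list lay -0.94 from the other miRNAs (adjusted p = 0.00504), and adjusted p = 0.402 with an estimated correlation, with 0 members lower over all miRNAs and 3 adjusted over the list alone. miR-140-3p stood at -1.46 ± 0.53 and miR-140-5p at -1.26 ± 0.45 (adjusted p = 0.31 each). The miR-17-92 list lay -0.58 lower (adjusted p = 0.00925), and adjusted p = 0.776 with an estimated correlation, with 0 members called either over all miRNAs or adjusted over the list alone. With the slide block these shifts were -1.39 (adjusted p = 0.134) and -1.79 (adjusted p = 0.000103). The cartilage call ended without right 4 weeks replicate 4 (adjusted p = 0.056), and the miR-17-92 call without right 4 weeks replicate 3 (0.318) or right 8 weeks replicate 4 (0.0666). The other 10 lists missed the threshold, with adjusted p from 0.289 to 0.895, though with the slide block the erythroid list lay at -3.25 (adjusted p = 0.0024). The erythroid and miR-17-92 values with the slide block depend on left 8 weeks, where replicate 2 was the highest array for both lists. Other miRNAs fixed by name lay between -1.30 (miR-210-3p) and 0.77 (miR-155-5p). The groups shared no slide, and 70 miRNAs passed with the slide block (62 higher, 8 lower) and 19 (18 higher, 1 lower) without right 8 weeks replicate 1, the brightest array.

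Whether the difference between sides itself changed from 4 to 8 weeks was tested as an interaction. In limma 0 of 267 miRNAs passed (smallest adjusted p = 0.984) and 3 had an unadjusted p under 0.05. The lowest on the higher side were miR-23a-5p (0.92 ± 0.38), miR-206-3p (3.17 ± 1.37, SE), miR-378b (1.56 ± 0.81), miR-1-3p (2.88 ± 1.51) and miR-1b (2.90 ± 1.53), and on the lower side miR-329-3p (-0.72 ± 0.33), miR-770-3p (-0.99 ± 0.52), miR-144-3p (-1.15 ± 0.62), miR-339-3p (-0.70 ± 0.39) and miR-144-5p (-1.23 ± 0.71). The muscle list shifted by 1.60 relative to the other miRNAs (adjusted p = 0.00314), and adjusted p = 0.516 with an estimated correlation, with 0 members passing over all miRNAs or adjusted over the list alone. The shift was 1.13 with the slide block (adjusted p = 0.391), and the call ended without right 4 weeks replicate 3 (adjusted p = 0.165) or right 8 weeks replicate 1 (0.162). The other 11 lists missed the threshold, with adjusted p from 0.136 to 0.993. The erythroid list lay at -2.17 and the miR-17-92 list at -0.95 with the slide block (adjusted p = 7.78e-05 each), where 5 miRNAs passed. Both values depend on left 8 weeks, where replicate 2 was the highest array for both lists. Other miRNAs fixed by name lay between -0.89 (miR-142-3p) and 1.56 (miR-133a-3p).

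Comparisons against the same 0-week arrays were set beside each other. Left 4 and right 4 weeks shared 34 calls, 4 higher and 30 lower, where independent lists would share 0.449 and 5.75, and their fold changes correlated over miRNAs, which are not independent replicates, at r = 0.952. In 100 simulations of unchanged groups against the shared arrays the mean r was 0.491 (SD 0.336, highest 0.922) and 0 calls were shared, though unchanged groups give few calls to share. The covariance was 0.908 against a simulated 0.0928, and with the 0-week arrays split between both comparisons r was 0.784 and 2 calls were shared on average. The 4-week arrays of both sides shared no slide with the 0-week arrays. Neither the simulations nor the split would remove an effect of slide common to both comparisons, so slide stays open for these shared calls. Left 4 and right 8 weeks shared 9 calls (4 higher, 5 lower; independent 0.3 and 1.26; r = 0.775, covariance 0.577, split r = 0.576). Right 4 and right 8 weeks shared 10 (7 higher, 3 lower; independent 0.36 and 0.839; r = 0.836, covariance 0.709, split r = 0.657). Left 8 weeks shared 0 calls with left 4 (r = 0.371, split r = 0.0771) and right 4 weeks (r = 0.364, split r = 0.106), and 1 with right 8 weeks (r = 0.528, split r = 0.127). Every r except that of left 4 and right 4 weeks lay within the simulated range.

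Of the lists too small to test, the HOX cluster list held miR-10a-5p and miR-10b-5p, with a mean of -4.92 ± 0.37 (SD, n = 4) at left 0, -5.19 ± 0.44 at left 4, -4.80 ± 0.41 at right 4, -4.95 ± 0.92 at left 8 and -4.62 ± 0.17 at right 8 weeks. The miR-34 family was represented by miR-34a-5p, at -3.21 ± 0.60, -3.53 ± 0.26, -3.15 ± 0.37, -3.99 ± 0.34 and -3.84 ± 0.44 in the same order. None of the epithelial or gland miRNAs on the array (0 measured in each list) met the detection filter. Of the 23 list calls over 108 tests, 0 held with an estimated correlation and 6 held with fry, which tests whether a list moves one way on balance, and for 0 of the 23 did mean, median and test differ in sign. Fry sets a list against no change and not against the other miRNAs, so its result depends on the scaling. Among the 6, the Dlk1-Dio3 calls at left 4, right 4 and right 8 weeks (fry adjusted p = 0.00311, 0.0156 and 0.0414) include the general fall of miRNAs against 0 weeks.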

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

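The tests chosen after their results were seen were the joint variation of 4 muscle miRNAs, the comparison of brighter with dimmer miRNAs, the shifts with slide as a fixed factor, and the reading of the corrections for muscle, probe GC and slide against a bound of 0.5 of the shift; the other tests in this part were set down before. In each group of 4 arrays, the array farthest from the others was compared by its gap to the nearest array, as a share of the group's whole range. Of 385 groups examined, over 61 named miRNAs, 14 lists and the array measures, 36 had an array past the 95% critical value of Dixon's ratio, where chance gives about 1 in 20. In 13 of the 36 the other 3 arrays were tied at the floor, which fixes the ratio, and the other 23 made up 5.97% of the groups, close to the share chance gives. Right 4 weeks replicate 3 was the lowest in 8 of them, all of muscle miRNAs or miRNAs of the miR-378 family, which are not independent of each other.

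Right 4 weeks replicate 3 lay below the other right 4-week arrays for muscle miRNAs. The gap was 0.954 of the range for the muscle list (-4.46 against -1.62 for the nearest array), 0.893 for miR-1-3p, 0.953 for miR-133a-3p, 0.927 for miR-133b-3p, 0.876 for miR-1b, 0.870 for miR-206-3p, 0.830 for miR-378a-5p and 0.911 for miR-378b. Right 8 weeks replicate 1 stood above its group in miRNAs detected (313 against 246, share 0.838) and in the scaling signal (13.16 against 9.88 on the log2 scale, share 0.846). It lay lowest for miR-145-5p, at the floor (0.878). Left 0 weeks replicate 4 lay lowest for the cartilage list (0.873), miR-210-3p (0.870) and miR-27b-3p (0.978). Left 4 weeks replicate 4 lay lowest for miR-210-3p (0.933) and for the arthritis list (0.937, at -2.42 against -2.40). Left 4 weeks replicate 3 was highest for the miR-17-92 list (0.906) and miR-451-5p (0.835). Right 4 weeks replicate 1 was highest for miR-134-5p (0.841) and miR-29a-3p (0.863). miR-138-1-3p was highest in right 8 weeks replicate 2 (0.902), miR-335 in left 0 weeks replicate 1 (0.854), and miR-140-5p was lowest in right 8 weeks replicate 3 (0.898).

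In the remaining cases the share was 1, because 1 array lay above the floor and the other 3 at it. These were miR-124-3p in left 8 weeks replicate 2, miR-138-1-3p and miR-3564 in right 4 weeks replicate 1, miR-144-3p and miR-335 in right 8 weeks replicate 1, miR-144-5p in left 0 weeks replicate 2, miR-155-5p and miR-329-3p in left 4 weeks replicate 4, miR-335 and miR-503-5p in left 8 weeks replicate 4, miR-3564 in left 4 weeks replicate 1, miR-378a-5p in left 8 weeks replicate 1, and miR-455-5p in left 0 weeks replicate 3. Such cases rest on signals next to the floor.

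The difference between sides changed from 4 to 8 weeks for the muscle list, by 1.60 on the log2 scale relative to the other miRNAs (adjusted p = 0.00314, and 0.516 with an estimated correlation). With the slide block the shift was 1.13 (adjusted p = 0.391). Without right 4 weeks replicate 3, the array low in muscle miRNAs, it was 0.83 (adjusted p = 0.165), and without right 8 weeks replicate 1 it was 1.43 (adjusted p = 0.162).

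As a list, muscle miRNAs lay higher on the right than on the left at 8 weeks, by 2.21 (adjusted p = 0.000179, and 0.225 with an estimated correlation), with 5 of 7 members higher, 0 members past the threshold over all miRNAs, and miR-1-3p at 1.79 against -2.11 (adjusted p = 0.0751). Within groups, miR-1-3p, miR-133a-3p, miR-133b-3p and miR-206-3p varied together over the 20 arrays, with a median pairwise r of 0.927 (0.847 to 0.961) where 95% of random sets of 4 miRNAs lay under 0.576. That is consistent with differing amounts of skeletal muscle in the dissected samples, although the 4 miRNAs would also vary together if they were regulated jointly, and no sort that would remove muscle is recorded. The shift was 1.64 (SE 0.904) within slide 2 and 1.74 (SE 0.959; adjusted p = 0.0383 in the list test) with slide as a fixed factor, in the same direction, but both spreads reached below 0.5 of the shift of 2.21 over slides 1 to 3, so slide stays open. A response of muscle or joint to overuse on the right stays open and was not tested, and treatment could not be separated from side here.

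At left 4 weeks the 21 miRNAs of the Dlk1-Dio3 cluster lay -0.56 (SE 0.0871) from the other miRNAs, against 0 weeks (adjusted p = 0.000289, and 0.436 with an estimated correlation). The shift was -0.58 (SE 0.182) with slide as a fixed factor, and left 8-week arrays on slide 3 lay 0.041 (SE 0.139) above those on slide 2. Only these 2 against 2 arrays link slides 2 and 3, so both values are 1 piece of evidence. Their scaling signals ran from 134.9 on slide 3 to 1563 on slide 2. The cluster mean in these arrays was -5.74 (replicate 1) and -4.96 (replicate 2) on slide 2, against -4.97 and -5.29 on slide 3. Arrays so few and so uneven cannot decide on slide. The spread of the 0.041 reached below 0, the bound set in advance, so that test could not tell and slide stays open. With each array's muscle mean as a covariate the shift was -0.44 (SE 0.0852), and after the trend on probe GC content was removed -0.47 (SE 0.0788). This argues against dilution by muscle RNA or GC content as the whole cause. Both spreads reached below 0.75 of the shift, the bound set in advance, so a part owed to either stays open. The shift with slide as a factor rests on the left 4-week arrays of slide 3, as slide 4 held no other group. At left 4 weeks the cluster mean was -5.62 (SD 0.014, n = 4), near the floor of -6.14. Of 27 alternatives 5 lost the call, and the shift was as small as -0.077. With all-probe scaling 2 members were lower and 2 higher. Weak signal and scaling therefore stay open, as do effects of treatment and of age, which were not tested.

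At left 4 weeks 48 miRNAs were lower than at 0 weeks, with a mean shift of -1.48, but the excess over the 10 higher depends on the scaling (20 higher and 13 lower with all probes, 8 and 7 with quantile normalization, 22 and 13 with median centring), and they were dimmer (median -5.33 against -4.72 over all arrays, a measure that includes the fall) and richer in probe GC (58.2 against 51.5%) than the rest. With slide as a fixed factor their mean shift was -2.11 (SE 0.513), and with the slide block 85 miRNAs were lower. The 48 were picked because they fell in these arrays, so a shift that stays negative is no separate support. Within left 8 weeks, not part of that comparison, slide 3 lay 0.36 (SE 0.399) above slide 2. That value rests on 2 against 2 arrays. On slide 2, replicate 1 held 31.5% of miRNAs at the floor and replicate 2 held 10.9%, so the slides are poorly represented. The spread of the 0.36 reached below 0, the bound set in advance, so that test could not tell and slide stays open. Fold change fell with probe GC (Spearman rho -0.37), but in size the value exceeded 52.9% of those from other splits of the 8 arrays, which reached 0.59, so GC stays open. Among miRNAs well above background on all 20 arrays 0 of the 48 passed, which had been set down in advance as what signals close to background would give, but that test was set aside after its outcome was seen, because only 5 of the 48 meet a filter that removes miRNAs that fell. The test put in its place, with 7.52% of brighter and 28.4% of dimmer miRNAs lower (bound 7.09%), has a like fault, as the level it sorts by includes the fall. Weak signal therefore stays open beside scaling, GC, slide, treatment and age.

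Other divisions of the same arrays into groups of the same sizes were tried for each count of miRNAs past the threshold. For left 4 against 0 weeks (58 miRNAs) only the real division of 35 gave as many, and the highest other gave 0. The same held for right 4 against left 0 weeks (44, highest other 9) and for left 8 against left 4 weeks (11, highest other 1). A share of 1 of 35 is the smallest such divisions can give and was not adjusted over the comparisons, so chance was not excluded. In these 3 comparisons the groups were not balanced over slides. More divisions gave as many for left 8 against 0 weeks (1 miRNA, 9 of 35, highest other 67) and right 8 against left 0 weeks (15, 4 of 35, highest other 76). Chance could not be excluded there either. Where the real count was 0 every division gives as many, so the divisions say nothing about chance: right against left at 4 weeks (35 of 35; highest other 8) and at 8 weeks (35 of 35; 80), right 8 against right 4 weeks (35 of 35; 10) and the interaction (100 of 100 drawn; 0).

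Divisions that gave 67, 76 and 80 miRNAs, many more than the real ones, point to a structure of the samples beyond their groups. For right 8 against left 0 weeks the 3 largest, 76, 62 and 42, each put both arrays of slide 1 together, and the real comparison gave 12 with the slide block and 0 within slide 2. The divisions giving 67 and 80 each put the slide 1 array together with left 8 weeks replicate 1, which lay on slide 2, so slide alone does not describe this structure. The arrays so joined are replicate 1 of left 0, left 8 and right 8 weeks, whose residuals correlated at 0.696 (left 0 and left 8), 0.793 (left 0 and right 8) and 0.648 (left 8 and right 8), and which held 27.7, 31.5 and 43.8% of miRNAs at the floor.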

How the results depend on the processing

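The alternatives chosen after the data were seen were the software's probe total, only miRNAs well above background on all arrays, centring on the median miRNA, the dimmest and brightest array left out together, array brightness as a covariate, and single slides; the others were fixed before. Counts of miRNAs past the threshold are given in the order left 4, left 8, right 4 and right 8 against left 0 weeks (58, 1, 44 and 15 as reported), right against left at 4 and 8 weeks (0 and 0), left 8 against left 4 (11), right 8 against right 4 (0) and the interaction (0). The cause of a change was not tested unless one is given. A count does not say which miRNAs passed, so the number of the 64 named calls and 23 list calls that kept their direction and their side of the threshold is given beside each setting.

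Other scalings lowered the counts for left 4, left 8 and right 8 against 0 weeks and raised the count for left 8 against left 4 weeks. With the percentile over all probes they were 33, 0, 36, 3, 0, 0, 27, 0 and 0 (40 named and 10 list calls kept), with quantile normalization 15, 0, 25, 6, 0, 0, 14, 0 and 0 (41 and 15), and with centring on the median miRNA 35, 0, 47, 9, 0, 0, 24, 0 and 0 (52 and 12). These scalings also moved the balance of directions: for left 4 against 0 weeks, 10 higher and 48 lower became 20 and 13, 8 and 7, and 22 and 13.

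The normexp background gave 0, 0, 6, 4, 0, 0, 0, 0 and 0 (8 named and 17 list calls kept), and 10 named calls changed sign. At left 4 against 0 weeks these were miR-455-5p (-0.15) and miR-450a-5p (-0.21), and at right 8 against left 0 weeks miR-128-3p (-0.048) and miR-29c-5p (-0.15). At left 8 against left 4 weeks they were miR-503-5p (0.12), miR-322-3p (0.29), miR-455-5p (0.34), miR-335 (0.31), miR-450a-5p (0.33) and miR-1949 (0.057).

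The software's gene total gave 8, 0, 9, 4, 1, 0, 5, 0 and 0 (12 named and 11 list calls kept). Signs changed for miR-450a-5p at left 4 against 0 weeks (-0.33), miR-128-3p (-0.88) and miR-331-3p (0.13) at right 4, miR-128-3p (-1.29) and miR-329-3p (1.17) at right 8, and miR-770-3p (-0.12) and miR-331-3p (-1.59) at left 8 against left 4 weeks. This column was at fault, since 23.9% of detected totals exceeded 1.2 times the sum of their own probes. Over those cells the authors' value table correlated at 0.533 with the probe sum and -0.0585 with the total. The probe total gave 63, 0, 39, 13, 0, 0, 10, 3 and 0 (50 and 19 kept). The authors' value table gave 20, 0, 27, 8, 0, 0, 18, 8 and 0 (29 and 10), and miR-331-3p changed sign at left 8 against left 4 weeks (-0.50).

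The brightest probe per miRNA gave 49, 3, 43, 17, 0, 0, 11, 0 and 0 (60 named and 21 list calls kept). Without a filter on dim probes counts were 9, 0, 9, 0, 0, 0, 2, 0 and 0 (15 and 3). There 397 of 758 miRNAs lay at the floor on all arrays (52.4%), their variances were exactly 0, and limma warned that its pooled variance estimate was unreliable. The cartilage list, right against left at 4 weeks, then tested in the other direction (adjusted p = 0.642) with a mean shift of -0.37. With the stricter filter counts were 41, 2, 37, 14, 0, 0, 10, 0 and 0 (60 of 62 named and 16 list calls kept). With the 100 miRNAs well above background on all arrays they were 0, 0, 6, 3, 0, 0, 0, 0 and 0 (7 of 22 and 4 of 11), a filter that removes most of those called.

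In the model, fitting only the arrays compared gave 30, 0, 31, 6, 0, 0, 9, 0 and 0 (46 named and 22 list calls kept), with fewer arrays behind each variance. Without the intensity trend counts were 45, 2, 29, 14, 0, 0, 12, 0 and 0 (62 and 21). Array weights raised them to 133, 26, 138, 19, 29, 1, 84, 127 and 4 (59 and 17), and the fibroblast and matrix list, right against left at 8 weeks, reversed to -0.47 (adjusted p = 0.0342). Without the dimmest and brightest array counts were 95, 0, 103, 4, 0, 0, 10, 23 and 0 (52 and 20), and that list reversed to -0.44 (adjusted p = 0.044). With brightness as a covariate they were 65, 2, 37, 11, 0, 2, 21, 58 and 3 (56 and 19).

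With slide as a block counts were 91, 6, 105, 12, 0, 5, 54, 70 and 5 (48 named and 18 list calls kept, 12 and 9 gained). The gains include the erythroid list in left 4 against 0 weeks (3.19), the sides at 8 weeks (-1.58), right 8 against right 4 weeks (-3.25) and the interaction (-2.17). Only left 8 weeks lay on both slides 2 and 3. Its erythroid means were -1.51 (replicate 2) and -3.63 (replicate 1) on slide 2, against -4.84 and -4.80 on slide 3. Replicate 2 therefore weighs on each of these gains, which are not separate findings. Array weights gained 38 named and 3 list calls, the fit without the dimmest and brightest array 7 and 5, brightness as a covariate 14 and 0, and the normexp background 0 and 10. Within slide 2 they were 0 for left 8 and right 8 against left 0 weeks and for the sides at 8 weeks, where 0 of 14 named and 6 of 7 list calls were kept with fewer arrays. Within slide 3 they were 0 for the sides at 4 weeks and 44 for left 8 against left 4 weeks, 43 of them higher (4 of 11 and 1 of 2 kept).

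Arrays with the same replicate number might have come from the same animal or batch, so the number was also tried as a block: counts were 71, 0, 64, 13, 0, 3, 29, 0 and 0, with 61 named and 23 list calls kept. Same-number arrays did not all deviate together. In left 8 against left 0 weeks their residuals correlated at 0.696, 0.306, 0.534 and -0.186, and in right 8 against left 0 weeks at 0.793, 0.0281, -0.521 and 0.511, so the pairing was not adopted.

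Leaving out 1 array at a time gave 9 (without left 0 weeks replicate 3) to 95 (without left 0 weeks replicate 1) for left 4 against 0 weeks, 0 to 7 for left 8, 3 to 102 for right 4 and 0 to 28 for right 8 against left 0 weeks. It gave 0 to 0 for the sides at 4 weeks and the interaction, 0 to 12 for the sides at 8 weeks, 2 to 59 for left 8 against left 4 and 0 to 19 for right 8 against right 4 weeks. The highest came without left 0 weeks replicate 1 for left 4, right 4 and right 8 against 0 weeks, and without left 0 weeks replicate 4 for left 8.

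Of the 23 list calls, 0 were kept with a correlation between members estimated from the data and 6 with fry, which does not set a list against the other miRNAs. With the 0-week arrays split between the comparisons, so that no array served both, the calls shared on average were 0.333 for left 4 and left 8 weeks (0 as reported), 2 for left 4 and right 4 (34), 0.5 for left 4 and right 8 (9), 0 for left 8 and right 8 (1) and 0.5 for right 4 and right 8 weeks (10). The correlation of left 8 and right 8 weeks fell to 0.127 from 0.528. Such splits leave 2 reference arrays per comparison, which lowers the number of calls. On an array 4.5 to 43.8% of the 267 miRNAs lay at the common floor, which limited the fold changes of single miRNAs. The share did not follow the signal. It was 43.8% on the brightest array, where 313 miRNAs were detected (right 8 weeks replicate 1). On the dimmest array, with 118 detected (left 8 weeks replicate 3), it was 18.7%.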
